A study of Mus musculus with 2 samples.

How the data were processed

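RNA from lung vascular cells of C57BL/6J mice was measured on 2 one-colour Affymetrix expression arrays, 1 from old and 1 from young mice. Per the labels' protocols, the left lung lobe was resected (pneumonectomy), vascular cells were flow-sorted from the remaining right lobes, RNA was extracted on silica columns, and biotin-labelled cRNA was made by in vitro transcription from an oligo-dT primed cDNA. The time after surgery, the ages, the sorting markers and the number of mice behind each array are not given in the sources used here, and arrays of unoperated mice were not analysed here. The number of arrays, 1 per group, limits the precision of every value.

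The deposited values are MAS5 intensity per probe set on a linear scale. The submitters' processing notes name GCOS 1.4 and MAS5. In the deposited intensity values the mean after trimming 2% at each end was 500.003 on both arrays, which is what MAS5 global scaling gives. Scanner images, probe-level intensities and detection calls were not used here. Of 45101 probe sets, 64 control probe sets were left out of all gene comparisons, which left 45037.

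Gene names came from the platform annotation of 2016 paired with the array's probe sets. In it 34958 probe sets had 1 gene symbol, 932 had several and 9211 had none, and only probe sets with 1 symbol were given a gene. Of these, 34754 were matched by Entrez identifier to current RefSeq gene names, and 0 symbols changed. Members of the gene lists were matched by symbol or current synonym. No genome build is named for the array values, so no coordinates are given.

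The arrays were scaled so that the median log2 ratio over probe sets above the floor on both arrays was 0. On the deposited values that median was -0.13 (old minus young), and the scale factors were 1.05 for the old and 0.956 for the young array. The floor was each array's median over non-control probe sets, the higher of both after scaling, which was 73.7 signal units. Values below it were treated as unordered. A gene was represented by its probe set with the highest mean log2 signal. With 1 array per group no statistical test was possible, so genes were counted by a fixed size rule of 2-fold. For a gene above the floor on 1 array only, the fold was computed against the floor and is a lower bound, and no fold is given for a gene below the floor on both. The spread of the log2 ratio between probe sets of the same gene, over 4514 genes with 2 or more probe sets above the floor on both arrays, was the only repeated measurement. It describes probe behaviour and not the mice.

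The rule for named genes, the gene lists and the alternatives below were fixed before the data were examined. Named genes were the 12 with the largest ratio in each direction among genes at 2 times the floor or more on both arrays whose probe sets had the same sign, then the 4 in each direction with the largest lower bound. They also included up to 4 members of each list with the largest absolute ratio. Named whatever their values were Nrp1, Epas1, Kdr, Flt1, Mmp14, Hgf, Cxcl12, Ackr3, Timp1, Pecam1, Cdh5 and Tek. Clones and predicted genes without a name were skipped. Any other gene named was chosen after its values were seen.

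The 55 lists covered cell types that the lung or the sort could hold, together with growth, signalling, stress, immune, metabolic and housekeeping gene groups. They held 728 genes, of which 665 were on the array. For each list the median log2 ratio was taken over members above the floor on at least 1 array, with the lower value set to the floor. It was placed among 10000 random lists of the same size matched on mean signal in 10 bins. A list outside the central 95% is described as above or below that range, as a description of these arrays. Lists with fewer than 3 measured members were not placed. A further 6 lists of liver, lung capillary and lymphatic genes were written after the data had been seen and are used mainly in the closing section, with the medians of 4 of them (liver sinusoidal, hepatocyte, liver macrophage and lung capillary) also given in the results.

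Alternatives were the values as deposited, equal trimmed means, quantile normalization, loess of the ratio on mean signal with a span of 0.4, floors at the 25 and 75 percentiles (the lower and the higher floor), the mean over a gene's probe sets, leaving out probe sets of the _x_at and _s_at kinds (which can match several transcripts and are called shared-sequence probe sets), a fixed fraction of the floor (0.5) added before log2 (the offset), unmatched random lists, and the list mean in place of the median. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, with figures drawn in matplotlib 3.10.9.

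The procedure was tested on simulated data made from the young and old signals with noise of the probe-set spread. The 2-fold rule was tried on changed genes with a mean signal of 4 times the floor or more, 50 of each size. It called 4% of genes changed 1.5-fold, 38% of those changed 2-fold, 98% of those changed 4-fold and 100% of those changed 8-fold. It called 1.75% of 10886 unchanged genes. A shift of 0.3 between the arrays was found as 0.301, and 2 of 50 unshifted lists lay outside the central 95%. The simulated noise was independent between probe sets. It held no variation between mice and no shared change of the genes of a list, so these rates cover probe-set noise only. The rates for changed genes do not cover genes nearer the floor.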

Results

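Gene expression was measured in vascular cells sorted from the right lung lobes of old and young C57BL/6J mice after the left lobe had been removed, an operation after which the remaining lung grows. The design compares the 2 ages, with 1 array from old and 1 from young mice. There is no replicate check for any difference reported here, and all log2 ratios are old minus young. Old and young name the arrays as labelled, and no measurement here checks the labels. The floor of 73.7 signal units was reached by 22519 probe sets on the old and 20901 on the young array, corresponding to 11450 and 10659 genes.

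The comparison asked how the lung vascular transcriptome differs with age after pneumonectomy. The old array had higher signal for immediate early genes such as Egr1 (121-fold) and Fos (110-fold), and for inflammatory and antigen presentation genes. Vascular endothelial growth factor (VEGF) receptors, co-receptors and ligands split, with 5 of 12 higher by 2-fold or more on the old and 4 on the young array. Flt1 (30.3-fold) and Nrp1 (26.8-fold) were on the old side and the co-receptor gene Nrp2 (3.02-fold) on the young. The young array had higher signal for mitosis genes such as Ube2c (7.20-fold), for cholesterol synthesis genes such as Sqle (6.19-fold), and for genes of lymphatic endothelium such as Prox1 (at least 93.4-fold). Markers of leukocytes, fibroblasts and mesothelium were also higher on the old array, with median log2 ratios of 3.16, 3.86 and 4.28. So were liver sinusoidal endothelial, hepatocyte and liver macrophage genes (medians 3.30, 2.84 and 3.32), in lists written after the data were seen. Of 10004 genes above the floor on both arrays, 1171 (11.7%) were 2-fold or more higher on the old and 1065 (10.6%) on the young array, and 7768 (77.6%) were within 2-fold. A further 766 genes on the old and 301 on the young array were at least 2-fold over the floor while below it on the other.

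**Figure D1:**
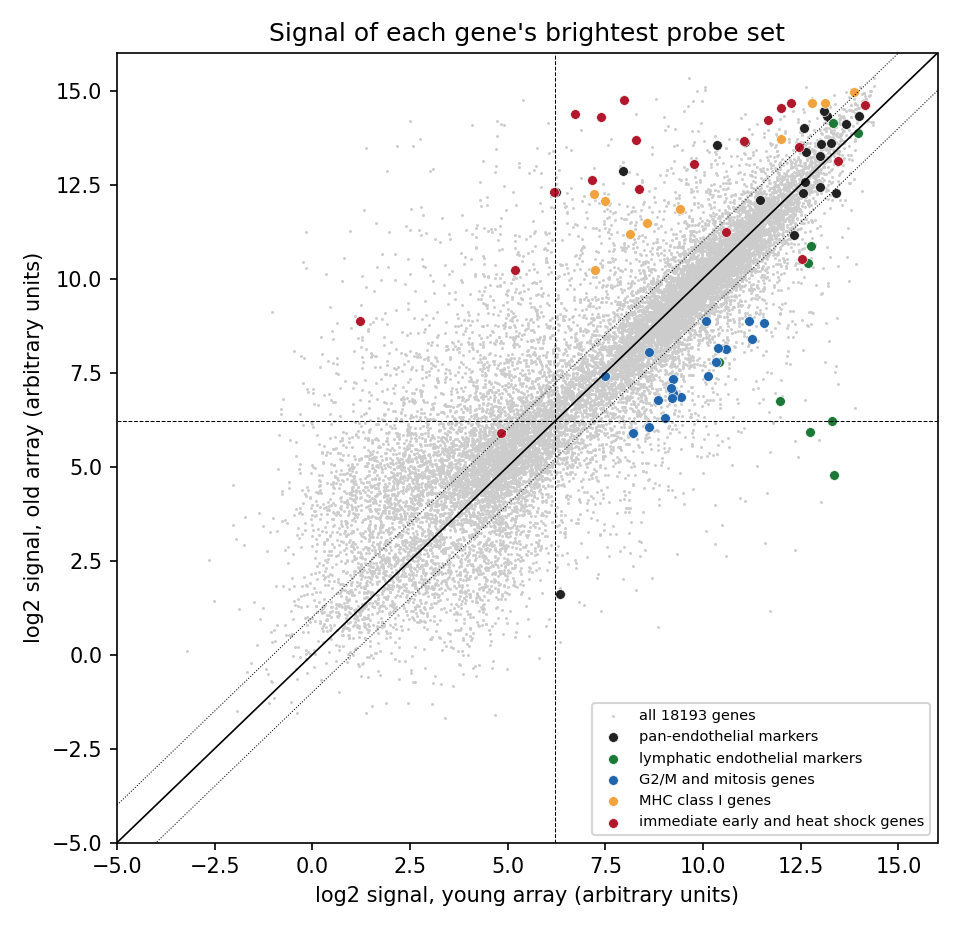
Log2 signal of 18193 genes on the young (x axis) and old (y axis) array, with 5 gene lists (pan-endothelial, lymphatic, mitosis, MHC class I, immediate early and heat shock) coloured, dashed lines at the floor, dotted lines at 2-fold and a solid line at equality. Mitosis and lymphatic genes lie mostly on the young side and MHC class I and immediate early genes on the old side, while 77.6% of genes above the floor on both arrays lie within 2-fold.

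The log2 ratio had an SD of 1.13 over genes above the floor on both arrays, and of 0.42 between probe sets of the same gene. Differences of 8-fold or more were found for 215 genes on the old and 99 on the young side. Of 811 genes at 2-fold or more with several probe sets, 753 (92.8%) had the same sign in all of them. The 3' to 5' signal ratio, a sign of RNA integrity, was 1.32 on the old and 1.20 on the young array for Actb and 0.718 and 0.806 for Gapdh. Across genes, which are not independent replicates, Pearson's r between the arrays was 0.796.

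Among genes well above the floor on both arrays, the largest ratios toward the old sample were those of Egr1 and Fos, transcription factors induced within minutes of stimulation, with signals of 20259 against 167 and 27753 against 251. They were followed by the granule proteoglycan gene Srgn (69.0-fold), Tcim (66.4-fold), the cytochrome P450 gene Cyp4b1 (63.2-fold) and the metallothionein gene Mt2 (62.8-fold). Exoc3l2 was 53-fold higher, the C-type lectin gene Clec4g 52.0-fold, the AP-1 gene Junb 42.1-fold and the GTPase gene Gimap4 39.1-fold. The deposited Clec4g value, 39321, was the highest of any non-control probe set on the old array. Clec4g is also known from liver sinusoidal endothelium. Gpihbp1, which holds lipoprotein lipase on capillary endothelium, was 35.7-fold higher and the small heat shock gene Hspb1 35.6-fold. Below the floor on the young array were Mrc1, the mannose receptor (at least 374-fold higher on the old), the ligand gene Bmp2 (at least 254-fold), the aminopeptidase gene Enpep (at least 252-fold) and the chemokine gene Cxcl10 (at least 243-fold). Alb, a hepatocyte transcript chosen after its values were seen, had a signal of 8900 on the old array and was below the floor on the young.

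Toward the young sample the largest ratios were those of Slc45a3 (58.0-fold), the neuropeptide gene Nmb (52.9-fold), Gpnmb (40.7-fold) and Aebp1 (30.0-fold). Sned1 was 25.9-fold higher on the young array, Dmtn 22.4-fold, the quinone reductase gene Nqo1 22-fold, Tm6sf1 21.6-fold and the proprotein convertase gene Pcsk6 20.7-fold. The list was completed by Tmem158 (20.0-fold), Mpp7 (19.1-fold) and the matrix gene Tnc (18.8-fold). The probe sets of Dmtn spread from -4.49 to -1.07 in log2 ratio. Below the floor on the old array were the neuropeptide gene Nts (at least 141-fold higher on the young), Tc2n (at least 112-fold), the collagen gene Col23a1 (at least 108-fold) and Prox1, the transcription factor of lymphatic identity (at least 93.4-fold).

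Genes of vascular growth and regeneration differed in both directions. Nrp1, a VEGF co-receptor, had a log2 ratio of 4.75 with probe sets from 4.59 to 4.88, and Flt1, a VEGF receptor, 4.92 with probe sets from 3.50 to 4.92. The receptor gene Tek was 5.91-fold, the membrane protease gene Mmp14 4.19-fold, the hypoxia-inducible factor gene Epas1 3.04-fold, Kdr 2.21-fold and Timp1 2.10-fold higher on the old array. The chemokine gene Cxcl12 was 13.5-fold higher on the old array, while its receptor gene Ackr3 was 3.75-fold higher on the young, by a single probe set of the shared-sequence kind. Hgf was at least 2.35-fold higher on the old array. Pecam1 and Cdh5, general endothelial genes, had log2 ratios of -0.04 and 0.33, and the probe sets of Cdh5 had opposite signs. Kdr was under 2-fold with quantile normalization (0.61) and loess (0.73), Epas1 with quantile normalization (0.99), Timp1 on the values as deposited and with equal trimmed means (0.94 in both) and with the lower floor (0.99), and Hgf with the offset (0.93). Cxcl12 had 1.34 with the higher floor and 1.42 over all its probe sets.

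Of 12 measured VEGF receptors, co-receptors and ligands, 5 were 2-fold or more higher on the old and 4 on the young array (median 0.83, above the random range of -0.36 to 0.61). The repulsive guidance gene Sema3a (at least 21.7-fold), the ligand gene Pgf (at least 20.8-fold) and the co-receptor gene Nrp2 (3.02-fold) were higher on the young. The median was 0.54 and within the range with the higher floor, and the list mean of 0.25 lay within its range. Of 18 angiocrine and lung regeneration factors, 9 were higher on the old and 6 on the young array (median 0.87, range -0.35 to 0.46). Bmp6 (27.7-fold) and Rspo3 (at least 15.8-fold) were on the old side, and Igf1, a growth factor, was 12.5-fold higher on the young, with probe sets from -3.94 to -2.19 in log2 ratio. The list mean of 0.57 lay within its range, and the median was 0.47 on the values as deposited and with equal trimmed means, 0.55 with quantile normalization and 0.52 with the lower floor. BMP and TGF-beta genes were higher on the old array for 10 of 16 members and on the young for 2 (median 1.51, range -0.33 to 0.43). They were led by the inhibitory Smads Smad6 (35.2-fold) and Smad7 (16.6-fold), Tgfbi (13.6-fold) and Id3 (10.4-fold), and the probe sets of Smad7 spread from 2.34 to 4.05. The Tgfbi value came from a shared-sequence probe set with a young signal of 76.9, just above the floor. Liver sinusoidal endothelial (median 3.30) and hepatocyte genes (2.84), from lists written after the data were seen, lay on the same side as these medians. The liver sinusoidal and angiocrine lists share Rspo3 and Wnt2.

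Endothelial subtype markers did not share a direction. General capillary markers were 2-fold or more higher on the old array for 7 of 10 members and on the young for 0 (median 2.82, range -0.42 to 0.64), with Kit (at least 103-fold), Gpihbp1 and the lipase gene Lpl (14.8-fold). In lists written after the data were seen, liver sinusoidal endothelial (median 3.30, 14 of 16 higher on the old), hepatocyte (2.84, 15 of 16) and liver macrophage genes (3.32, 8 of 8) lay on the same side, while further lung capillary genes had a median of -0.03, within the range of -0.56 to 0.82. Among these lung capillary genes Car4, Fibin and Tbx3 were below the floor on both arrays, and Foxf1, Scn7a and Tmem100 had low signals. Their median therefore does not show unchanged expression. Arterial markers were higher on the old for 4 of 8 and on the young for 1 (median 1.54, range -0.64 to 0.86). Sox17 was 67.5-fold and the Notch ligand gene Dll4 13.8-fold higher on the old array, and the kinase gene Bmx at least 5.30-fold higher on the young. The Sox17 value came from a shared-sequence probe set with a young signal of 74.9, just above the floor. Lymphatic markers were higher on the young array for 7 of 9 members and on the old for 0 (median -2.62, range -0.45 to 0.66). These included Nts, Mmrn1 (135-fold), Prox1 and Reln (37.6-fold), although Reln had a log2 ratio of -0.65 over all its probe sets. Mmrn1 had a signal of 74.6 on the old array, just above the floor, so its fold is close to a lower bound.

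Pan-endothelial markers had 7 of 20 members higher on the old and 2 on the young array (median 0.50, range -0.14 to 0.48), with Robo4 9.12-fold higher on the old. That median was within the range under quantile normalization (0.01), loess (0.12), both other floors (0.42 and 0.56) and the mean over probe sets (0.43). Aerocyte markers split, with 4 of 7 higher on the old and 3 on the young array (median 1.14, range -0.57 to 0.87). Tbx2 was 13.9-fold and Emp2 at least 7.22-fold higher on the old, and Chst1 20.0-fold and the endothelin receptor gene Ednrb 8.83-fold higher on the young. The list mean was -0.15, opposite in sign to the median, and the median was within the range under quantile normalization (0.54), loess (0.70), the higher floor (0.12) and the mean over probe sets (0.70). Venous markers were higher on the old for 4 of 10 and on the young for 1 (median 0.21, within the range of -0.50 to 0.83), with Ackr1 at least 47.9-fold higher on the old. The venous median had the opposite sign under quantile normalization (-0.15) and loess (-0.06), and was above the range over all probe sets (0.83) and as a mean (1.24).

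**Figure D2:**
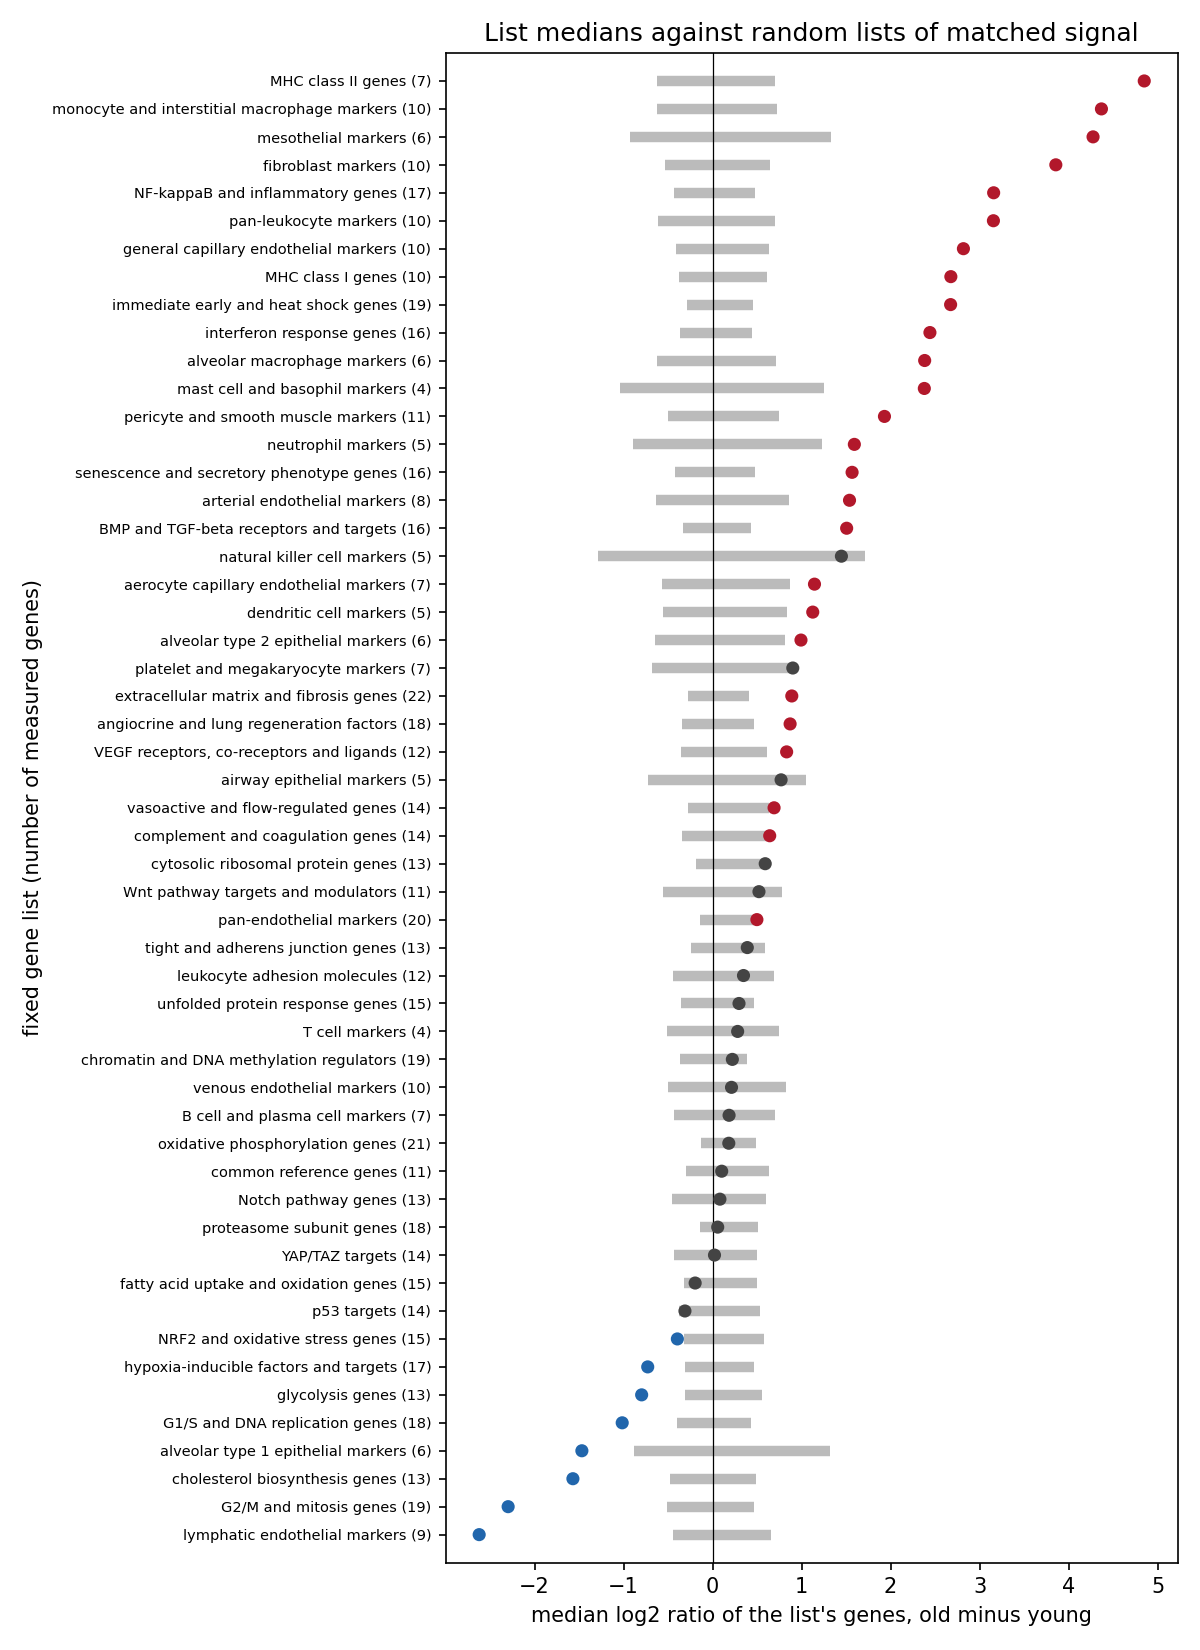
Median log2 ratio (old minus young) of 53 gene lists as dots, red above, blue below and dark within the grey bars, which span the central 95% of random lists matched on signal. The lists outside are 26 above and 8 below, and the lymphatic (-2.62) and mitosis (-2.30) lists lie lowest.

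Markers of the other cell types that the lung or the sort could hold were mostly on the old side. Fibroblast markers were higher on the old array for 8 of 10 members (median 3.86, range -0.54 to 0.65), among them the collagen genes Col3a1 (at least 118-fold) and Col1a2 (at least 110-fold). Pericyte and smooth muscle markers were higher on the old for 8 of 11 (median 1.93, range -0.50 to 0.75), led by the actin gene Acta2 (134-fold) and Tagln (55.8-fold). All 6 measured mesothelial markers were higher on the old (median 4.28, range -0.92 to 1.33), with Upk3b at least 49.8-fold and Lrrn4 at least 34.2-fold. Monocyte and interstitial macrophage markers were higher on the old for 9 of 10 (median 4.37, range -0.62 to 0.72), with the receptor gene Csf1r 77.2-fold and the complement gene C1qa at least 38.7-fold. The probe sets of Csf1r spread from 3.10 to 6.27 in log2 ratio, and its young signal of 75.6 lay just above the floor. Lyz1 and Lyz2, near-identical lysozyme genes whose probes may not separate them, were at least 98.4-fold and at least 56.5-fold higher on the old array.

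Pan-leukocyte markers were higher on the old array for 8 of 10 members and on the young for 0 (median 3.16, range -0.61 to 0.70), with Fcer1g at least 62.3-fold and Ptprc, which encodes CD45, at least 19.0-fold. Alveolar macrophage markers had 3 of 6 members higher on the old and 1 on the young (median 2.38, range -0.62 to 0.71), namely Mrc1, Fabp1 (at least 32.2-fold) and Marco (at least 14.5-fold) against Pparg (11-fold). Mrc1 is also known from sinusoidal endothelium and Fabp1 from hepatocytes, and Marco is also in the liver macrophage list written after the data were seen. The alveolar macrophage markers Siglecf, Car4, Cidec and Krt79 were below the floor on both arrays. Mast cell and basophil markers had a median of 2.38 (range -1.04 to 1.25) from 4 measured members, of which Kit and Hdc (24.9-fold) were higher on the old and Cpa3 (at least 3.21-fold) on the young. It was 0.07 and within the range with the lower floor, and 0.12 without shared-sequence probe sets. Kit is also in the general capillary list. The mast cell and basophil markers Mcpt8, Mcpt4, Ms4a2, Fcer1a and Tpsb2 were below the floor on both arrays. Neutrophil markers had a median of 1.59 (range -0.89 to 1.23) with 3 of 5 members higher on the old, S100a8 (at least 14.3-fold) among them, and Lcn2 (16.7-fold) on the young. It was within the range with either other floor (0.86 and 0.69), without shared-sequence probe sets (0.98) and as a mean (1.03). The neutrophil markers Cxcr2, Mmp8, Mmp9, Camp and Ltf were below the floor on both arrays. Dendritic markers were higher on the old for 3 of 5 (median 1.13, range -0.56 to 0.83), led by Zbtb46 (7.58-fold), and were within the range under quantile normalization (1.01), loess (0.98) and the lower floor (1.05). The dendritic markers Flt3, Xcr1, Cd209a and Siglech were below the floor on both arrays.

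Natural killer (1.45), T cell (0.28), B cell and plasma cell (0.18) and platelet (0.90) markers had medians within their random ranges, and the T cell mean had the opposite sign (-0.05). On the old array 4 of 5 natural killer, 0 of 4 T cell, 1 of 7 B cell and 3 of 7 platelet markers were 2-fold or more higher, against 1, 1, 0 and 1 on the young. Natural killer markers were above their range with the lower floor (1.78), over all probe sets (1.44), as a mean (1.52) and against unmatched lists. Platelet markers were above theirs over all probe sets (0.90), as a mean (1.52), with the offset (0.81), against unmatched lists and without shared-sequence probe sets. Among the platelet markers Clec1b, a C-type lectin receptor gene, was at least 194-fold higher on the old array. Its signal there was 14305, against 659 for Pf4, the next highest of the platelet markers. Epithelial markers went different ways. Alveolar type 2 markers were higher on the old for 3 of 6 (median 0.99, range -0.64 to 0.82). These were Etv5 (6.51-fold), Napsa and Lyz1, whose probes may not separate it from Lyz2. The type 2 median lay within the range with the higher floor (0.12), over all probe sets and without shared-sequence probe sets (0.75 in both). Sftpc, Sftpa1, Slc34a2, Muc1 and Cxcl15, also type 2 markers, were below the floor on both arrays. Alveolar type 1 markers were higher on the young for 4 of 6 and on the old for 2 (median -1.47, range -0.88 to 1.32), with Clic5 at least 11.5-fold higher on the young and Igfbp2 at least 28.6-fold on the old, and lay within the range with the lower floor (-0.36) and as a mean (-0.29). The type 1 members on the young side included Pdpn, also in the lymphatic list, and Vegfa, also in the VEGF and hypoxia lists. Aqp5, Rtkn2, Cldn18 and Akap5, also type 1 markers, were below the floor on both arrays. Airway markers were higher on the old for 2 of 5 (median 0.77, within the range), with the keratin genes Krt18 (at least 35.3-fold) and Krt8 (at least 30.8-fold) on the old side. They were above the range with the higher floor (2.22), over all probe sets (1.15), without shared-sequence probe sets (1.37) and as a mean (2.27). The airway markers Scgb1a1, Scgb3a2, Foxj1 and Krt5 were below the floor on both arrays. Erythroid markers had only 1 measured member, Car2 (1.55-fold higher on the old), and sex-linked genes 2, Xist (1.12-fold higher on the old) and Eif2s3y (at least 1.5-fold higher on the old).

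Immediate early and heat shock genes were higher on the old array for 15 of 19 members and on the young for 1 (median 2.67, range -0.28 to 0.45). The RNA-decay gene Zfp36 was 203-fold and the nuclear receptor gene Nr4a1 at least 68.8-fold higher. Inflammatory NF-kappaB genes were higher on the old for 14 of 17 (median 3.16, range -0.43 to 0.48), with the chemokine gene Cxcl1 87.6-fold, Cxcl2 at least 29.7-fold and the cyclooxygenase gene Ptgs2 at least 24.4-fold. The probe sets of Cxcl1 spread from 2.64 to 6.45 in log2 ratio, and its young signal of 75.7 lay just above the floor. Interferon response genes were higher on the old for 11 of 16 (median 2.44, range -0.37 to 0.44), with Irf1 19.4-fold and Oasl2 at least 18.0-fold. All 10 measured MHC class I genes were higher on the old (median 2.68, range -0.38 to 0.61), with the immunoproteasome gene Psmb8 33.0-fold, although B2m was under 2-fold on the values as deposited (0.98) and with equal trimmed means (0.99), quantile normalization (0.38) and loess (0.56). MHC class II genes were higher on the old for 5 of 7 (median 4.85, range -0.63 to 0.71), with H2-Aa at least 59.3-fold and the invariant chain gene Cd74 29.1-fold. Pan-leukocyte markers, with the median of 3.16, lay on the same side as all of these groups.

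Senescence and secretory phenotype genes were higher on the old array for 10 of 16 members and on the young for 1 (median 1.57, range -0.42 to 0.47). The named members were the cytokine and chemokine genes Il1a (at least 159-fold), Cxcl1, Cxcl2 and Il1b (at least 15.8-fold), while Cdkn2a, a cell-cycle inhibitor gene chosen after its values were seen, was 5.76-fold higher on the young. Pan-leukocyte (3.16) and monocyte and macrophage markers (4.37) lay on the same side as the list. Extracellular matrix and fibrosis genes were higher on the old for 11 of 22 members and on the young for 5 (median 0.89, range -0.27 to 0.41). Col3a1, Lox (at least 111-fold), Col1a2 and Col1a1 (at least 37.1-fold) led them, and fibroblast markers, with the median of 3.86, lay on the same side. Complement and coagulation genes had 5 of 14 members higher on the old and 3 on the young (median 0.64, range -0.34 to 0.63). The protein C receptor gene Procr (14.0-fold) and the plasminogen activator genes Plat (13.8-fold) and Plau (7.50-fold) were higher on the young. That median was within the range with the higher floor (0.25) and as a mean (0.10), and hepatocyte (2.84) and liver sinusoidal genes (3.30) lay on the same side. Vasoactive genes were higher on the old for 5 of 14 and on the young for 3 (median 0.69, range -0.27 to 0.63), with Ptgis at least 13.2-fold and Klf2, a flow-responsive factor, 4.84-fold higher on the old. They were within the range with the higher floor (0.40), over all probe sets (0.48) and as a mean (0.30). Pericyte and smooth muscle markers (1.93) and liver sinusoidal genes (3.30) lay on the same side.

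Genes of cell division were on the young side, as were lymphatic markers (median -2.62). Pan-leukocyte markers (3.16) were on the old side, as were liver sinusoidal (3.30) and hepatocyte genes (2.84), from lists written after the data were seen. Mitosis genes were higher on the young array for 17 of 19 members and on the old for 0 (median -2.30, range -0.52 to 0.47), with the ubiquitin-conjugating gene Ube2c 7.20-fold, the kinesin gene Kif11 6.72-fold, Cdc20 6.58-fold and the cyclin gene Ccnb2 6.57-fold higher. DNA replication genes were higher on the young for 9 of 18 and on the old for 0 (median -1.02, range -0.40 to 0.43), with Ccne2 5.77-fold and Rrm2 4.84-fold. Cholesterol synthesis genes were higher on the young for 11 of 13 and on the old for 0 (median -1.57, range -0.47 to 0.49), with Sqle and Idi1 (5.84-fold) the furthest. Glycolysis genes were higher on the young for 4 of 13 and on the old for 1 (median -0.80, range -0.31 to 0.56), with Hk2 3.76-fold higher on the young and Pfkp 3.13-fold on the old. Hypoxia-inducible factors and targets were higher on the young for 5 of 17 and on the old for 2 (median -0.73, range -0.31 to 0.47), with Egln3, an oxygen sensor gene, at least 27.3-fold and Vegfa 4.30-fold higher on the young. NRF2 and oxidative stress genes were higher on the young for 4 of 15 and on the old for 3 (median -0.40, range -0.32 to 0.58), with Nqo1 on the young and Gpx3 (at least 23.1-fold) on the old side. It was 0.06 with the higher floor and 0.14 over all probe sets, and lay within the range as a mean (-0.23) and against unmatched lists.

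**Figure D3:**
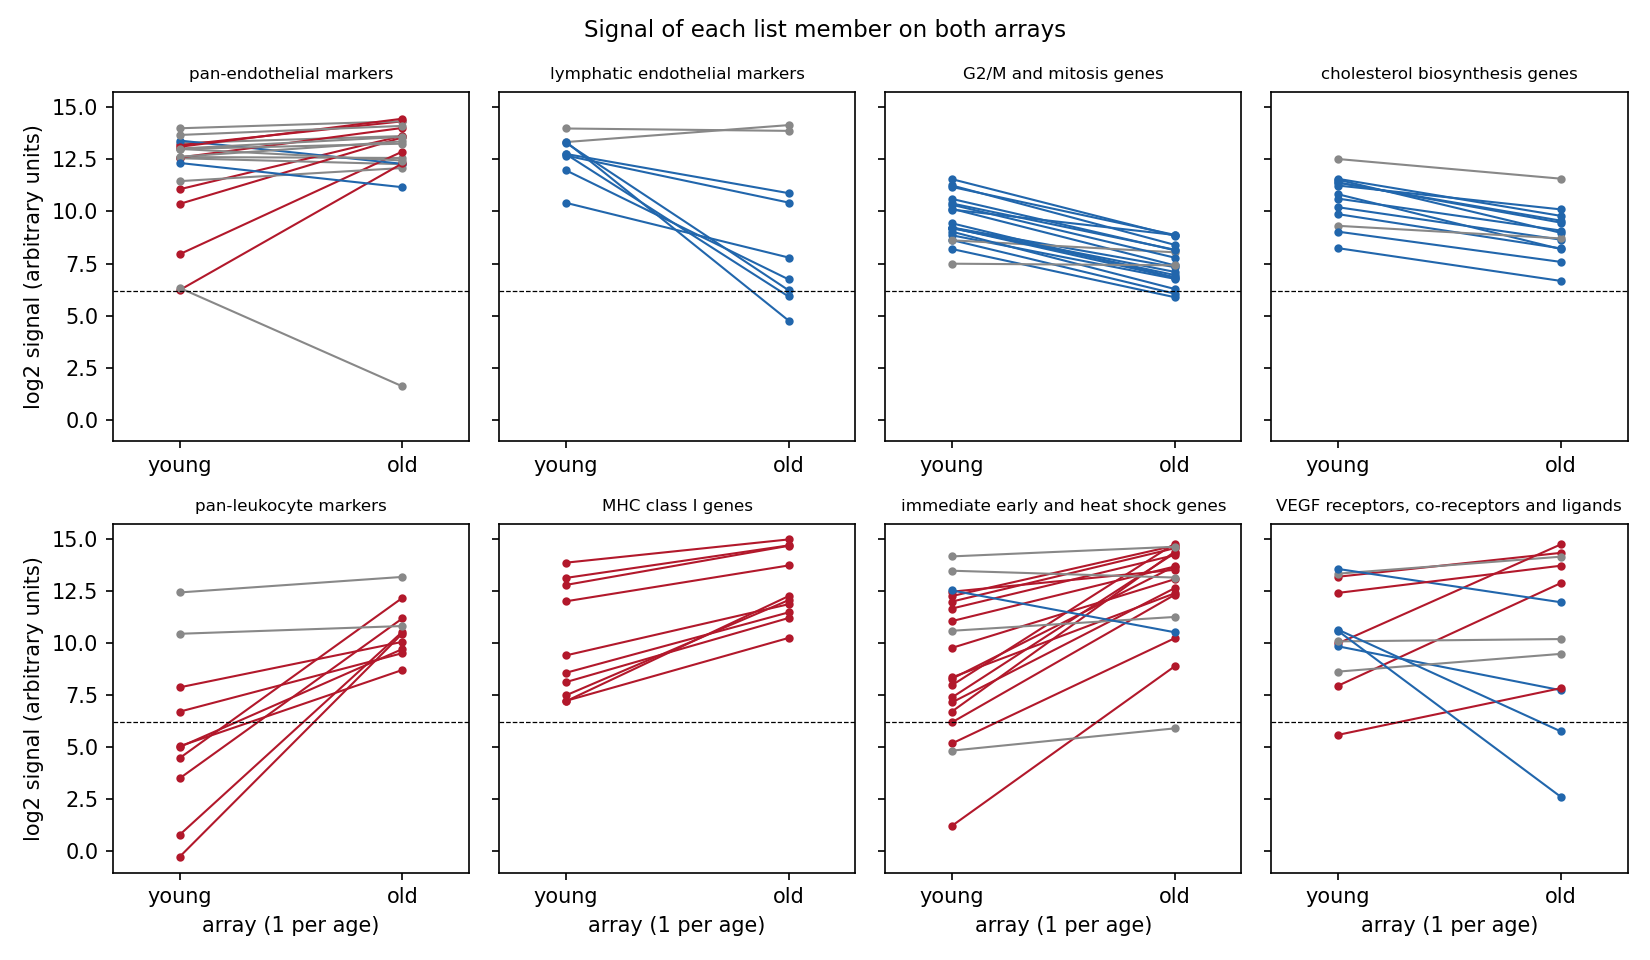
Log2 signal of the members of 8 gene lists on the young and old array, 1 line per gene, red if 2-fold or more higher on the old, blue if lower, grey if within 2-fold, with the floor dashed. Of 19 mitosis genes 17 are blue, and of 10 pan-leukocyte markers 8 are red.

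Several groups lay within their random ranges. All 21 oxidative phosphorylation genes (median 0.18), all 18 proteasome genes (0.06) and all 13 ribosomal protein genes (0.59) were within 2-fold. The ribosomal median was above the range of unmatched lists and had the opposite sign under quantile normalization (-0.11). Fatty acid genes, of which 4 of 15 were higher on the old and 2 on the young, had a median of -0.20 and a mean of 0.98, the latter above its range, with the fatty acid transporter gene Cd36 110-fold and Pdk4 at least 54.1-fold higher on the old. Notch genes (4 of 13 higher on the old, 3 on the young) had 0.08, with Notch4 43.7-fold higher on the old and Notch2 2.88-fold on the young, and lay below the range over all probe sets (-0.51). Wnt genes (4 of 11 and 2) had 0.52, with Dkk3 at least 10.6-fold higher on the old and the receptor gene Fzd6 6.92-fold on the young. YAP/TAZ targets (3 of 14 and 5) had 0.02, with Axl 16-fold higher on the old and Myof 5.21-fold on the young. Leukocyte adhesion genes (5 of 12 and 2) had 0.35, with Vcam1 at least 27.7-fold and Icam1 14.6-fold higher on the old and Cd34 5.81-fold on the young, and were above the range as a mean (1.01). Targets of p53 (1 of 14 and 3) had -0.31, with Fas 10.6-fold higher on the old and Phlda3 3.09-fold on the young. They were below the range under loess (-0.39), the higher floor (-0.33), the mean over probe sets (-0.52) and without shared-sequence probe sets (-0.44). Unfolded protein response genes (1 of 15 and 2) had 0.30, with Herpud1 3.45-fold higher on the old and the asparagine synthetase gene Asns 4.15-fold on the young. Junction genes (1 of 13 and 2) had 0.39, with Esam 2.68-fold higher on the old and Jup 2.28-fold on the young. Chromatin genes (2 of 19 and 1) had 0.22, with the methyltransferase gene Ezh2 3.40-fold higher on the young. Common reference genes (1 of 11 and 2) had 0.10 and a mean of -0.17, and the transferrin receptor gene Tfrc was 8.25-fold higher on the young but had a log2 ratio of -0.24 over all its probe sets. The signs of the reference, YAP/TAZ, Notch, proteasome, adhesion and oxidative phosphorylation medians changed under other scalings.

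Of the 53 lists placed, 34 lay outside the central 95% of random lists, 26 above and 8 below, where 2.65 would be outside by chance if genes varied independently. That number does not allow for genes that vary together within a list or for genes shared between lists. The ratios describe 1 array per age and include no spread between mice. Some medians kept their side of the range but moved by over 1.5 times. With the higher floor they were 1.77 for general capillary, 1.12 for pan-leukocyte, 2.35 for monocyte and 2.14 for mesothelial markers, -0.85 for alveolar type 1 markers, 2.45 for MHC class II, 1.88 for NF-kappaB and 0.81 for senescence genes, and -1.17 for mitosis and -0.49 for DNA replication genes. With the lower floor arterial markers had 0.80 and pericyte markers 3.41, and over all probe sets general capillary markers had 1.86 and pan-leukocyte markers 1.23. With quantile normalization VEGF genes had 0.43, vasoactive genes 0.46, matrix genes 0.48 and NRF2 genes -0.65, and the means of the pan-endothelial, alveolar type 2 and matrix lists were 1.03, 1.94 and 1.35. Lower bounds depend on the floor chosen, and with the higher floor Ccne2, Kif11, Clic5, Emp2, Etv5, Dkk3, Ptgis, Pfkp and Vegfa, like Emp2, Reln, Notch2 and Myof over all probe sets, were under 2-fold.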

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

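All tests in this part were chosen after the results had been seen. The poly-A controls, bacterial transcripts added to the RNA before labelling and outside the gene comparisons, had a median log2 ratio of 2.98 (7.86-fold higher on the old array, 24 probe sets, SD 0.41). Scaling or hybridization as the whole cause is argued against by the hybridization controls, which are added later and had a median of 0.45 (SD 0.50, 18 probe sets), 2.53 below the poly-A controls. RNA degradation is argued against by the 3' to 5' ratios of Actb and Gapdh, whose larger value on the old relative to the young array was 1.10. All 4 poly-A transcripts were higher, the lowest median being 2.66, so less sample RNA per amount of control may underlie the old array. The age of the mice, the only biological difference the design names, was not tested.

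Among 10092 probe sets without a single gene name, 1666 were above the floor on both arrays and 311 (18.7%) differed by 2-fold or more, 181 higher on the old and 130 on the young, which drew attention because no comparison used them.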

How the results depend on the processing

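No alternative was added after the results were seen. No test of other splits or of leaving out replicates could be run with 1 array per group. No paired analysis was possible because there is 1 array per group and the labels carry no replicate numbers. With the floor at the 25 percentile 1927 genes were 2-fold or more higher on the old and 1651 on the young array. At the 75 percentile these were 535 and 356, and 453 genes were at least 2-fold over the floor on the old array only. A lower floor admits more genes and a higher floor fewer, by construction. All other counts stayed within 1.5 times those reported. Genes higher on the old array made up 44.5% of the 2-fold genes on the values as deposited, against 52.4% as reported and 60.0% with the higher floor. Lists outside the random range numbered 27 to 36, and the probe-set SD was 0.312 to 0.589. That SD has no value for the mean over probe sets, and the counts against the floor were not planned with the offset. Of 53 lists, 32 kept their position relative to the random range under every alternative, 12 lost a position outside it and 9 gained one under some alternative, and 0 moved to the opposite side. Of 196 named genes at 2-fold or more, 159 were so in every alternative that gave a value, and 0 changed sign. Signal over the floor limits what can be seen, since 6088 genes were below it on both arrays.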

Other observations

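The tests in this part were chosen after the results had been seen, as were the genes and lists named, apart from Ednrb, Cdkn2a as a list member, and the pan-endothelial, pan-leukocyte, lymphatic marker and mitosis lists. Homeobox genes of the Hoxd cluster, which mark position along the body axis, were above the floor on the young array for 4 of 8 members and on the old for 0. Hoxd8 was at least 75.2-fold, Hoxd9 at least 70.9-fold, Hoxd10 at least 45.4-fold and Hoxd3 at least 4.01-fold higher on the young array. In the Hoxa cluster 4 of 9 genes were 2-fold or more higher on the old array, Hoxa5 by 12.3-fold, and 1 on the young, Hoxa7 by at least 3.83-fold. In the Hoxb cluster 3 of 9 were higher on the old, Hoxb5 by 6.93-fold, and 0 on the young, and in the Hoxc cluster 0 of 7 on either. Of 11 additional lymphatic genes, 6 were 2-fold or more higher on the young and 2 on the old array (median -1.60, range -0.41 to 0.73). They included Tbx1 (at least 41.3-fold), Foxc2 (at least 28.7-fold) and Klhl4 (5.11-fold).

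Further lung capillary genes had a median of -0.03 (range -0.56 to 0.82) over 6 measured members. Of 9 on the array, 5 were above the floor on the old and 3 on the young. Hpgd was at least 151-fold higher on the old and Ednrb 8.83-fold on the young. Car4, Fibin and Tbx3 were below the floor on both. Whether these probe sets respond was not tested.

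Liver sinusoidal endothelial genes had a median of 3.30 (range -0.26 to 0.53), and all 16 were above the floor on the old array against 11 on the young, with Fcgr2b at 33136 against 1068 and Ehd3 at 26903 against 863. Of the 16, 8 are also known from lung, 3 are in the lists fixed earlier, and 7 of the other 8 were 2-fold or more higher on the old. Lung vascular cells as the only source is argued against by the hepatocyte genes, of which 15 of 16 were above the floor and 2-fold or more higher on the old (median 2.84), with Alb at 8900. RNA of liver vascular cells may be present in the old array, since 14 of 16 sinusoidal genes were 2-fold or more higher there. Liver macrophage genes (3.32, Vsig4 at 2707, Clec4f at 2442) and stellate genes (2.07) lay on the same side. The stellate list says little by itself, because Lrat and Lhx2 were below the floor on both arrays. Its members Dcn, Des and Hgf are also in the fibroblast, pericyte and angiocrine lists. The labels, moreover, give lung and a vascular sort whose gate is not stated. Age, with 1 array per age, and a mislabelled or exchanged sample cannot be told apart from such a source. On the old array 5 of 9 lung capillary genes were above the floor. That count cannot decide on an exchange, because 11450 of all 18193 genes were above the floor there. A wrong label would change what every ratio here compares, the Hoxd and lymphatic genes of the young array included.

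Mitosis genes were lower on the old array. Dilution by RNA of non-endothelial cells alone would lower endothelial genes alike. It is argued against on these arrays, because the pan-endothelial median lay 2.80 (SE 0.57) above that of the mitosis genes. The SEs in this paragraph are taken over list members, which are not independent replicates, and include no error between samples. Dilution by RNA of other endothelial cells, such as those of liver, would leave pan-endothelial genes in place and stays open, since the lymphatic median differed from that of the mitosis genes by -0.33 (SE 1.28) while its members spread with an SD of 3.03. Growth of the young cells in culture before extraction may contribute, since Cdkn2a had a log2 ratio of -2.53 and 6 of 10 pan-leukocyte markers were below the floor on the young array, although a sort would also remove leukocytes and the labels describe no culture. The age of the mice remains open and untested.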
